A study of Mus musculus with 6 samples.

How the data were processed

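RNA was measured in subcutaneous tumours grown in CD1 nude mice from injected transformed hepatoblasts, the progenitors of hepatocytes and bile duct cells. The cells carried a vector from which doxycycline switches on a short hairpin RNA (shRNA) against St18, a zinc finger transcription factor. Per the labels' protocols, doxycycline was given by oral gavage as a first dose of 200 mg/ml in 300 µl of water, and the animals were killed after 4 h. RNA was extracted from frozen tissue, depleted of ribosomal RNA with Ribo-Zero, and made into libraries with the Illumina TruSeq RNA kit v2. Groups were taken from the treatment label: 3 untreated libraries, whose genotype label is wild type, and 3 libraries taken 4 h after doxycycline, whose genotype label is ST18 knockdown. The labels describe no animals given doxycycline without the hairpin, so drug, gavage and hairpin differ together between the groups. The design text speaks of triplicates, and nothing says outright that each library came from a separate animal. If they did not, the p-values measure only the spread between these libraries.

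The deposited table holds read counts per gene, which the authors produced with TopHat2 2.0.8, TopHat and HTSeq on mouse build mm9, per the submitters' processing notes, which give neither the role nor the order of the tools. Strand use, treatment of multiply mapped reads and removal of duplicate reads are not given in the sources used here. Whether reads from a gene and an overlapping antisense gene were told apart is therefore unknown, and close paralogs (Myh1, Myh2 and Myh4, or the actin and globin genes) are uncertain. The values are whole numbers that sum to different totals, as raw counts do. The table has 21761 rows, of which 90 carry no gene name. These held 0.0361% to 0.0402% of each library's counts and stayed out of library sizes and of the tests between groups. Of the 21671 named genes, 1218 had no count in any library. Total counts per library were 13148155, 16169043 and 14801770 for untreated replicates 1, 2 and 3, and 12090309, 14344216 and 15899374 for doxycycline replicates 1, 2 and 3. The top 10 genes took 0.948% to 1.09% of the counts. The reference used here is another mouse build than the authors' mm9. It served only for GC content, exonic length and gene synonyms, and no coordinates are printed.

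Counts of the most abundant genes levelled off. No gene with at least 1000 exonic bases exceeded 1.59 counts per base in its untreated mean, and 52 genes lay above 1. The deepest untreated library held 1.23 times the counts of the shallowest. The median ratio of these libraries per gene was 1.23 for genes at 0.05 to 0.1 counts per base and 1.08 for genes above 1. Eef1a1 had 2840, 2966 and 2867 counts in the untreated libraries. Fold changes of abundant genes may therefore be compressed, and normalised counts of such genes understate their level. The replicates of each group differed by more than sampling noise (chi-square per degree of freedom 5.17 to 8.28 between untreated libraries and 12.4 to 29.8 between doxycycline libraries), so each was counted as its own sample.

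Differential expression was tested on the deposited counts in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, libraries were scaled by TMM (factors 0.985 to 1.02), and groups were compared with the robust quasi-likelihood test (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A positive log2 fold change means higher after doxycycline. Standard errors are the log2 fold change divided by the square root of F, and intervals are 95% intervals from the t distribution with the test's degrees of freedom. Normalised counts are given as CPM, scaled by the TMM-adjusted library totals. Levels are means ± SD over the 3 libraries of a group. Counting intervals are binomial intervals on the pooled reads of each group. They leave out the spread between libraries and are too narrow where libraries differ.

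Fixed before the data were examined were the test, the rule for named genes, 33 gene lists and all alternatives except those stated below to be added. The named genes are St18 with its relatives Myt1 and Myt1l, then the 12 largest positive and the 12 largest negative log2 fold changes. These had to have an adjusted p under 0.05, no overlap between the groups and a mean of at least 1 CPM in the higher group, and symbols of predicted genes, clones, pseudogenes and small RNAs were left out. Each list described adds up to 4 members with the smallest p. The lists cover the ST18 family; NF-kB and inflammatory cytokine, immediate early, interferon, hypoxia, integrated stress response, endoplasmic reticulum chaperone, heat shock, glucocorticoid, circadian, p53, apoptosis, ribosome biogenesis and MYC, epithelial-mesenchymal transition, TGF-beta, growth factor, cholesterol and fatty acid, and mitosis and replication genes. Others hold markers of macrophages, neutrophils, dendritic cells, lymphocytes, endothelium, fibroblasts and mural cells, skeletal muscle, adipocytes, keratinocytes, red cells and the hepatic lineage, and mitochondrial, ribosomal protein, histone and nuclear RNA genes. Of 617 list entries, 579 matched a symbol in the table, 1 matched through a synonym and 37 were absent. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation and fry, whose p asks whether a list's genes move one way on balance. Camera with an estimated correlation also uses only the residual degrees of freedom of the libraries. A call lost there therefore cannot be put down to correlation between genes alone. Counts "adjusted over the list alone" repeat the adjustment within a list. After seeing the data, 6 lists were added: aminoacyl-tRNA synthetases, amino acid transporters, mast cell, Schwann cell, tendon and fascia, and Y-linked genes.

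The code was tested on simulated data: 14663 genes in 3 against 3 libraries, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 61% of the 2-fold and 91% of the 4-fold changes, and 12 of 164 calls were false. The simulation drew genes independently and gave both groups the same spread per gene. These rates therefore check the code and may not hold for the real libraries. Alternatives were DESeq2's size factors and upper quartile scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with sample quality weights, a replicate block and each library left out. Further ones were removal of mitochondrial, ribosomal RNA and haemoglobin genes, a threshold of 0.1, and omission of muscle, adipocyte, keratinocyte and erythroid list genes from the counts. Offsets for GC content and transcript length, from smooth fits with mgcv 1.9.3, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.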

Results

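The series measured gene expression by ribosome-depleted RNA sequencing in subcutaneous mouse tumours of transformed hepatoblasts. It compared 3 libraries from untreated tumours with 3 libraries from tumours taken 4 h after doxycycline, which switches on an shRNA against St18. Totals ran from 12090309 to 16169043 counts per library. The comparison asks which genes differ between these groups, in which drug, gavage and hairpin differ together.

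St18, the gene the hairpin targets, was not lower in the libraries labelled ST18 knockdown. Its counts were 12, 23 and 19 in untreated replicates 1, 2 and 3, and 34, 12 and 61 in doxycycline replicates 1, 2 and 3. This corresponds to 1.21 ± 0.276 CPM and 2.50 ± 1.53 CPM (SD, n = 3 each). The log2 fold change was 1.03 (SE 0.55, 95% interval -0.22 to 2.29, edgeR quasi-likelihood test, adjusted p = 0.298), so the difference did not exceed the spread between libraries. Without doxycycline replicate 2 the log2 fold change was 1.45 and passed the threshold (adjusted p = 0.0386). A fall of the target was therefore not seen in these libraries, and every direction below is between the untreated libraries and those labelled ST18 knockdown. The related zinc finger genes Myt1 (log2 fold change -1.49, adjusted p = 0.121) and Myt1l (0.36, adjusted p = 0.648) did not pass the threshold. For the 3 genes of the family together, camera gave an adjusted p of 0.886. The median log2 fold change was 0.36, while the mean of -0.03 and the test pointed down. Adjusted over the list alone, Myt1 was lower.

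**Figure D1:**
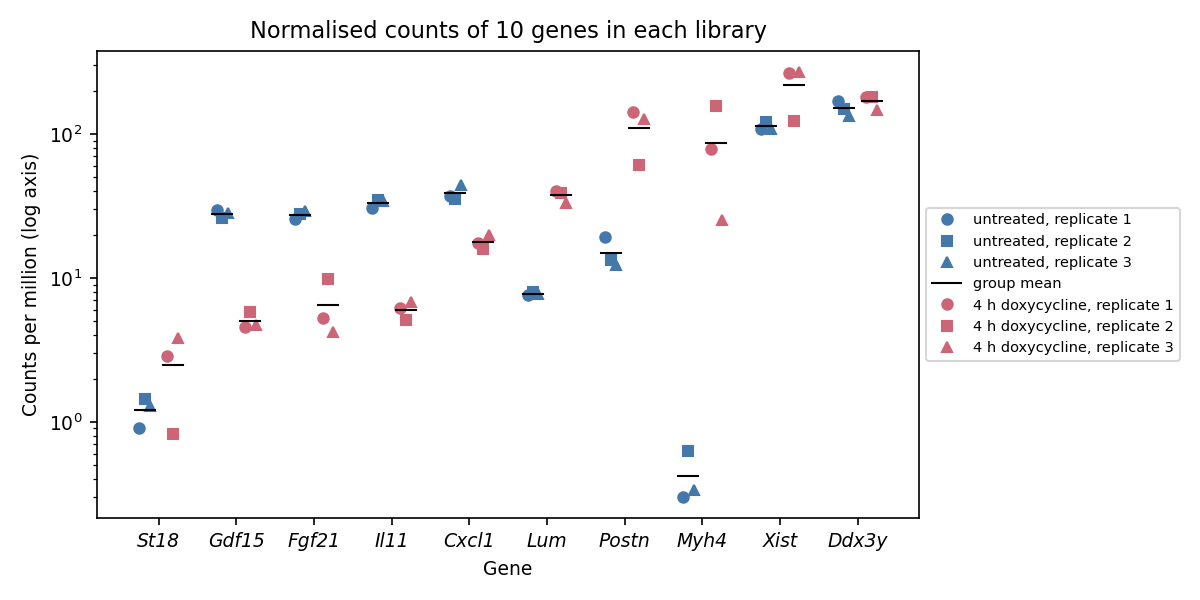
Normalised counts (CPM) on a log axis for 10 genes, with 1 point per library (circle, square and triangle for replicates 1, 2 and 3), untreated libraries in blue, libraries taken 4 h after doxycycline in red, and black lines for group means. St18 averages 1.21 CPM untreated and 2.50 CPM after doxycycline with overlapping points, Gdf15 and Il11 lie lower in every doxycycline library, and Lum, Postn and Myh4 lie higher.

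Across the transcriptome, 421 genes were higher and 323 lower in the libraries labelled ST18 knockdown, of 14809 tested. The largest increases among the named genes were those of Myh4, Xirp2 and Cthrc1 (the last over 4 untreated counts), and the largest decreases those of Ccl20, Etv2 and Vgf. Of the 12 named genes with the largest increases, 2 (Myh4 and Pvalb) are in the muscle list. Xirp2, Xirp1, Myot, Mybpc1, Trdn and Car3, described with the muscle markers below, are outside that list. The median size of the log2 fold change was 1.22 among the higher and 0.59 among the lower genes. An unadjusted p under 0.05 was reached by 3535 genes (23.9%), and the groups did not overlap for 4382 genes (29.6%, against 10% by chance). The first principal component (44.9% of the variance) separated the groups, and the second (27.6%) separated doxycycline replicate 2 from doxycycline replicates 1 and 3. Genes that were higher had a median GC content of 46.1% and genes that were lower 54.5%, against 49.9% for all. With offsets for GC content and length, chosen after seeing the data, 281 genes were higher and 347 lower, of which 249 and 229 were shared with the uncorrected calls. The numbers depended on which libraries were included, and fell most when any 1 untreated library was left out. They fell to 11 higher and 12 lower without untreated replicate 1, to 27 and 25 without untreated replicate 2, and to 14 and 13 without untreated replicate 3. They were 180 and 236 without doxycycline replicate 1, 159 and 130 without doxycycline replicate 3, and 1244 and 866 without doxycycline replicate 2. Without untreated replicates 1, 2 and 3, an unadjusted p under 0.05 in edgeR was still reached by 2414, 2748 and 2158 genes.

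Skeletal muscle markers had the largest median change of the lists. Of 15 muscle markers tested, 9 were higher and none lower, with a median log2 fold change of 3.29, and all 15 were higher adjusted over the list alone. Myh4, a fast myosin heavy chain, went from 0.423 ± 0.179 to 87.0 ± 65.9 CPM (log2 fold change 7.63, SE 0.81, edgeR adjusted p = 0.00546). Pvalb, the calcium buffer of fast fibres (5.60, adjusted p = 0.0213), Myh2 (4.68, adjusted p = 0.021) and Myl1 (4.34, adjusted p = 0.029) rose too. Pvalb had 4 untreated counts in all, against 205 after doxycycline (ratio 53.1, 95% counting interval 20.4 to 197). Its edgeR 95% interval, which includes the spread between libraries, was 3.43 to 7.77 in log2 units. Among the 12 genes with the largest increases were the sarcomere-associated genes Xirp2 (6.14), Xirp1 (5.02), Myot (5.34) and Mybpc1 (4.92), Trdn, which encodes triadin of the sarcoplasmic reticulum (5.30), and Car3 (5.18), a carbonic anhydrase of muscle and fat. The summed CPM of the muscle list was 38.7, 68.7 and 31.4 in untreated replicates 1 to 3 and 442, 735 and 118 in doxycycline replicates 1 to 3. Camera called the list higher (adjusted p = 1.71e-15), which was lost with an estimated correlation (adjusted p = 0.46). In edgeR, 0 markers passed without each of untreated replicates 1, 2 and 3 (12, 14 and 13 at an unadjusted p under 0.05) and 2 without doxycycline replicate 1 or with no filter on low counts, while DESeq2 called 14 and limma-voom 7 on all libraries. The list median was 3.64, 4.23 and 2.92 without untreated replicates 1, 2 and 3.

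The fibroblast markers Lum, Dcn and Postn rose in the same libraries, and most of their list did not pass the threshold. Of 16 fibroblast and mural cell markers, 3 were higher and none lower (median log2 fold change 0.60; adjusted over the list alone, 10 higher and 1 lower). The small proteoglycan Lum rose from 7.79 ± 0.244 to 37.5 ± 4.01 CPM (log2 fold change 2.26, edgeR adjusted p = 0.00174), Dcn by 2.22 (adjusted p = 0.00519) and the matrix protein Postn by 2.88 (adjusted p = 0.00655). Acta2, smooth muscle actin, was at 0.67 and did not pass (adjusted p = 0.0598). The abundant collagen gene Col3a1 was at 514 ± 14.9 and 579 ± 19.7 CPM. The fibroblast list was called higher by camera (adjusted p = 9.15e-09), which was lost with an estimated correlation (adjusted p = 0.248), while fry gave an adjusted p of 0.0354. Also among the 12 largest increases were the matrix genes Cthrc1 (6.07) and Thbs4 (4.84), the ephrin receptor Epha3 (5.19) and Tmem100 (4.96). Tmem100 had 3 counts over the untreated libraries and 99 over the doxycycline libraries, a ratio of 34.2 (95% counting interval 11.4 to 169). Cthrc1 had 0, 0 and 4 untreated counts against 284 over the doxycycline libraries (ratio 73.5, interval 28.4 to 272), so its fold rests on untreated replicate 3. The edgeR 95% intervals in log2 units, which include the spread between libraries, were 2.90 to 7.02 for Tmem100 and 3.84 to 8.30 for Cthrc1. In the same libraries 9 of 15 muscle markers were higher (median 3.29). Without any 1 untreated library 2 fibroblast markers passed, and without doxycycline replicate 2 there were 7.

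A few macrophage markers were higher. Of 23 tested, 3 were higher and none lower (median 0.33; 7 higher adjusted over the list alone): Mrc1, the mannose receptor (0.95, edgeR adjusted p = 0.024), the haemoglobin scavenger receptor Cd163 (0.69, adjusted p = 0.0357) and Emr1, which encodes F4/80 (0.82, adjusted p = 0.0395). Ctss was at 0.63 (adjusted p = 0.0598). In the same libraries 9 of 15 muscle and 3 of 16 fibroblast markers were higher. Camera called the list higher (adjusted p = 0.00272), but not with an estimated correlation (adjusted p = 0.646) and not without doxycycline replicate 3 (adjusted p = 0.104).

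**Figure D2:**
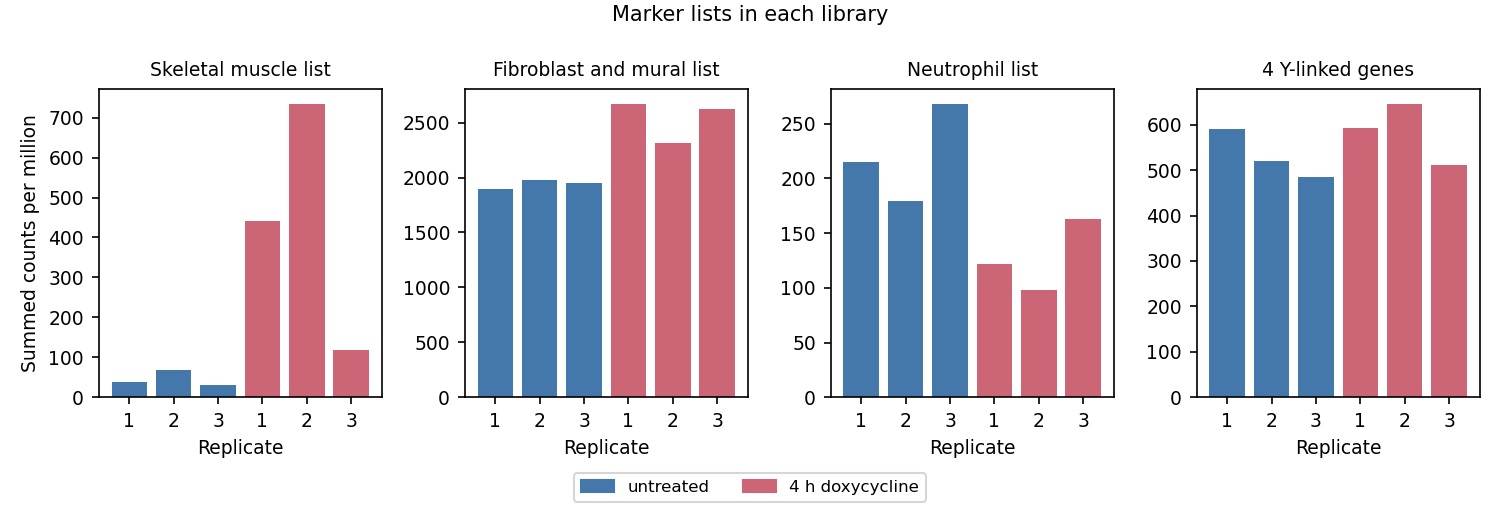
Bars give the summed CPM of 4 marker lists in each library (replicates 1 to 3), untreated in blue and 4 h after doxycycline in red. The muscle sum is highest in doxycycline replicate 2 (735) and the fibroblast sum in doxycycline replicate 1 (2672), the neutrophil sum is lower in every doxycycline library, and the Y-linked sum overlaps between groups.

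Genes of the integrated stress response, the programme driven by ATF4 when amino acids run short or protein folding fails, fell together. Of 20 tested, 17 were lower and none higher, with a median log2 fold change of -0.80, and all 20 were lower adjusted over the list alone. Gdf15, a stress-induced secreted factor, fell from 27.9 ± 1.82 to 5.00 ± 0.673 CPM (log2 fold change -2.47, SE 0.20, edgeR adjusted p = 0.00174). The folate enzyme Aldh1l2 (-0.87, adjusted p = 0.00413), the transcription factor Atf5 (-1.04, adjusted p = 0.00546) and the leucine sensor Sesn2 (-1.46, adjusted p = 0.00655) fell as well. So did the hormone gene Fgf21, which went from 27.5 ± 1.70 to 6.46 ± 3.02 CPM (-2.09, adjusted p = 0.0154). Atf4 itself, with Psat1 and Phgdh, did not pass the threshold over all genes. The whole list was called lower by camera (adjusted p = 8.76e-37), and of the lists fixed before the data were examined it was the only one whose call held with an estimated correlation (adjusted p = 0.0369). Fry gave an adjusted p of 0.00219. In the same libraries 9 of 15 muscle markers (median 3.29) and 3 of 16 fibroblast markers (median 0.60) were higher, and 1 of 13 neutrophil markers was lower (median -1.05). These marker shifts stand beside every list described below as well, including the lists chosen after seeing the data. The number of members past the threshold was 3, 5 and 4 without untreated replicates 1, 2 and 3, and 10 without doxycycline replicate 3, while the median lay between -0.77 and -0.83 under every alternative fit.

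**Figure D3:**
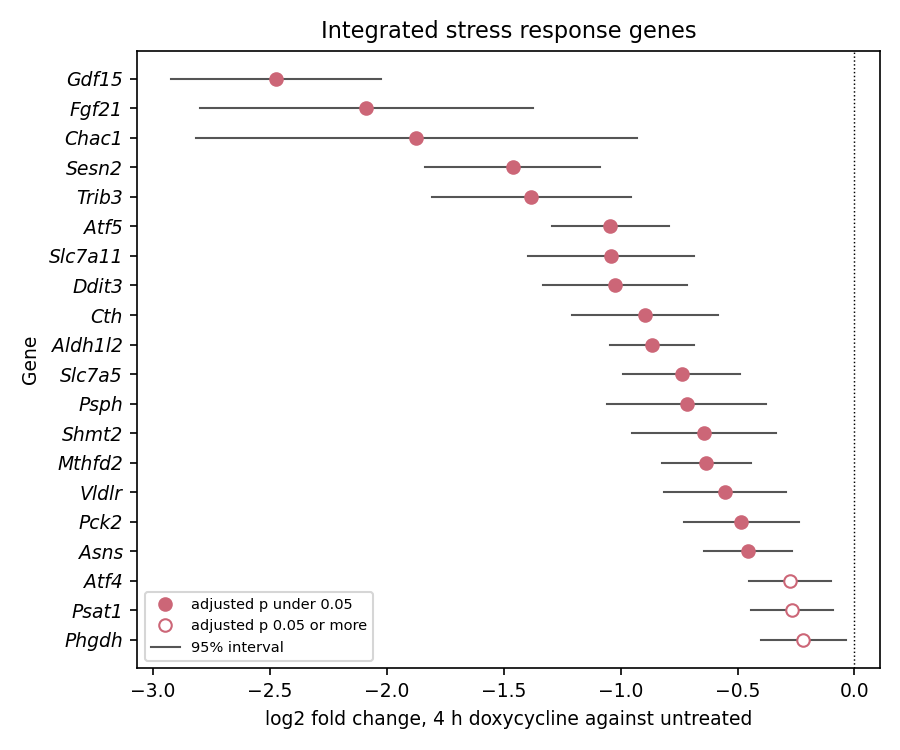
Log2 fold changes (x axis) of the 20 integrated stress response genes (y axis), 4 h after doxycycline against untreated, with 95% intervals as lines, filled points for an adjusted p under 0.05 and open points otherwise. All 20 points lie below 0, from Gdf15 at -2.47 to Phgdh at -0.22, and 17 are filled.

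Some genes of the endoplasmic reticulum chaperone and hypoxia lists were lower. Of 14 endoplasmic reticulum chaperone genes, 3 were lower and none higher (median -0.13; 5 lower adjusted over the list alone): Hyou1 (-0.62, edgeR adjusted p = 0.0164), Herpud1 (-0.48, adjusted p = 0.0264) and Sdf2l1 (-0.86, adjusted p = 0.0371). Creld2 was at -0.45 (adjusted p = 0.0661). Camera called the list lower (adjusted p = 8.32e-04), which was lost with an estimated correlation (adjusted p = 0.46). Of 19 hypoxia response genes, Ddit4, an inhibitor of mTORC1 (-0.78, adjusted p = 0.0164), and the angiogenic factor Vegfa (-0.71, adjusted p = 0.0446) were lower (median -0.48; 10 lower adjusted over the list alone). The glucose transporter Slc2a1 (-0.79, adjusted p = 0.0587) and Eno1 (-0.54, adjusted p = 0.0572) did not pass. Camera called this list lower as well (adjusted p = 5.99e-08), again not with an estimated correlation (adjusted p = 0.46).

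Some inflammatory genes, and the neutrophil receptor Csf3r, were lower. Of 32 NF-kB and inflammatory cytokine genes, 6 were lower and none higher (median -0.63; 13 lower and 1 higher adjusted over the list alone). The neutrophil attractant Cxcl1 fell from 39.1 ± 4.78 to 17.7 ± 1.99 CPM (log2 fold change -1.14, edgeR adjusted p = 0.0132). Relb (-0.78, adjusted p = 0.023), Tnfaip2 (-0.48, adjusted p = 0.0249), the chemokine Ccl20 (-3.21, adjusted p = 0.0409), Nfkb2 (-0.64, adjusted p = 0.0419) and Ccl2 (-0.76, adjusted p = 0.0454) also fell. The NF-kB list was called lower by camera (adjusted p = 6.27e-10), but not with an estimated correlation (adjusted p = 0.46). Of 13 neutrophil markers, 1 was lower, the receptor Csf3r (-1.55, adjusted p = 0.0486), and all 13 had negative values (median -1.05; 4 lower adjusted over the list alone). S100a8 (-1.42, adjusted p = 0.0529), S100a9 (-1.21, adjusted p = 0.0754) and Retnlg (-1.59, adjusted p = 0.114) did not pass. Camera called the neutrophil list lower (adjusted p = 2.53e-05), but not with an estimated correlation (adjusted p = 0.46).

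A few interferon response and immediate early genes were lower. Of 24 type I interferon response genes, 3 were lower and none higher (median -0.78; 18 lower and 2 higher adjusted over the list alone): the antiviral protein gene Rsad2 (-1.30, edgeR adjusted p = 0.0247), the chemokine Cxcl10 (-1.81, adjusted p = 0.0288) and Ifi44 (-1.18, adjusted p = 0.0358). Irf7 was at -0.93 (adjusted p = 0.0558). The interferon list was called lower by camera (adjusted p = 1.47e-08), which was lost with an estimated correlation (adjusted p = 0.46). Of 25 immediate early genes, 4 were lower and none higher (median -0.51; 8 lower adjusted over the list alone). These were the AP-1 subunit Junb (-0.51, adjusted p = 0.0233), Ier3 (-0.81, adjusted p = 0.0233), Ier5 (-0.54, adjusted p = 0.0323) and the phosphatase Dusp5 (-0.85, adjusted p = 0.0453). Immediate early genes were called lower by camera (adjusted p = 6.44e-08), again not with an estimated correlation (adjusted p = 0.46). In the same libraries 1 of 13 neutrophil markers was lower (median -1.05).

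Some ribosome biogenesis genes were lower by small amounts. Of 18 ribosome biogenesis and MYC target genes, 5 were lower and none higher (median -0.19; 7 lower adjusted over the list alone), among them the RNA polymerase I subunit Polr1b (-0.50, edgeR adjusted p = 0.0126), Cad, which starts pyrimidine synthesis (-0.52, adjusted p = 0.0164), Bop1 (-0.49, adjusted p = 0.0212) and Srm (-0.61, adjusted p = 0.0274). Camera called the list lower (adjusted p = 4.62e-06), but not with an estimated correlation (adjusted p = 0.46). Of 20 cholesterol and fatty acid synthesis genes, Lss was lower (-0.45, adjusted p = 0.0426), none was higher, and 19 had negative values (median -0.22; 1 lower adjusted over the list alone). Sqle (-0.34, adjusted p = 0.0715), Srebf1 (-0.30, adjusted p = 0.092) and Fasn (-0.40, adjusted p = 0.112) did not pass. Camera called this list lower (adjusted p = 3.56e-04), again not with an estimated correlation (adjusted p = 0.46).

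The other genes with the largest decreases belonged to none of these lists. Il11, a cytokine of the IL-6 family, fell from 33.2 ± 2.23 to 6.02 ± 0.86 CPM (log2 fold change -2.46, edgeR adjusted p = 0.00174). Decreases were also found for the vascular transcription factor gene Etv2 (-2.89), the secreted neuropeptide precursor Vgf (-2.82), Apol11b (-2.66), the homeobox gene Hoxb9 (-2.09), Extl1 (-2.08), the peptide hormone gene Adm2 (-2.01), the protease inhibitor Slpi (-2.00) and the actin regulator Avil (-2.00), with adjusted p from 0.00737 to 0.0432. Of 66 genes past the threshold among those followed by the naming rule, Gdf15, Il11, Aldh1l2, Lum and Dcn stayed past it whichever library was left out. Without untreated replicates 1, 2 and 3 the threshold was lost by 60, 56 and 57 of the 66, and without doxycycline replicates 1, 2 and 3 by 33, 3 and 31.

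The remaining lists were not called by camera (adjusted p from 0.0614 to 0.979). Proliferation genes showed little movement: of 30 mitosis and DNA replication genes, Cenpf was higher (0.40), Cdt1 was lower (-0.55), and the median was -0.06. The medians were 0.16 for 18 hepatoblast, hepatocyte and biliary markers, 0.10 for 17 epithelial-mesenchymal transition genes, -0.05 for 27 cytosolic ribosomal protein genes and -0.14 for 26 replication-dependent histone genes, with no member past the threshold. The same held for 14 dendritic cell and MHC class II genes (0.57), 6 T, NK and B cell markers (0.35), 3 adipocyte markers (0.58), 6 keratinocyte and skin markers (-0.01) and 6 erythroid genes (-0.30). Among 13 endothelial markers (0.27), the receptor Tek (1.31) and Cdh5 (0.51) were higher. Among 16 TGF-beta response genes (0.08), Ltbp2 (2.19), Tgfb2 (1.20) and Tgfb3 (0.48) were higher. Of 16 p53 target genes (0.02), Trp53inp1 (1.21) and Sesn1 (0.75) were higher, and of 21 apoptosis regulators (0.12), Bcl2 (0.50) was higher. Among 15 circadian clock genes (0.12), Tef (0.77) and Nr1d2 (0.42) were higher and Nfil3 (-0.96) was lower. Of 14 heat shock genes (-0.06), Hspa1b (-1.08) and Hsph1 (-0.44) were lower. Of 24 growth factors and receptors (-0.28), Igf1 (2.90) and Lifr (0.55) were higher and Ccl2 (-0.76) was lower. For 15 glucocorticoid response genes, of which Pdk4 was higher (3.28), the median (0.18) and mean (0.21) were positive and the test pointed down. For 9 nuclear RNA markers, none past the threshold, the median (-0.03) was negative, while the mean (0.22) and the test pointed up. Adjusted p values for the single genes named here lay under 0.05 in the edgeR test. Adjusted over the list alone, higher and lower members numbered 4 and 1 for dendritic cell, 2 and 0 for endothelial, 1 and 0 for adipocyte, 2 and 1 for mitosis, 0 and 3 for heat shock and 3 and 3 for glucocorticoid genes. They numbered 4 and 3 for circadian, 2 and 3 for p53, 1 and 0 for apoptosis, 4 and 0 for TGF-beta, 2 and 6 for growth factor and 2 and 0 for nuclear RNA genes, and 0 in both directions for the others. The mitochondrially encoded list had no tested member.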

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

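The tests of the mitosis genes, of the muscle and fibroblast orders across libraries, of the ratio between doxycycline libraries and of group membership were chosen only after the result was seen, as was the added GC correction. Of 37 rows without a gene name that could be tested, 1 passed an adjusted p of 0.05 in an edgeR fit that included these rows; it is a signal in rows that the comparison of named genes leaves out. It had 13, 7 and 9 counts in the untreated and 61, 42 and 47 in the doxycycline libraries (log2 fold change 2.43, adjusted p = 0.0249). The row was not identified here.

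Integrated stress response genes were lower in the libraries labelled ST18 knockdown. GC content and transcript length bias is argued against, since with offsets for both the list's median was -0.778 and 14 of 20 genes were past the threshold. Fewer tumour cells per specimen stays open. The mitosis and DNA replication list had a median of -0.057 (bootstrap interval -0.139 to 0.0191). This interval may be too narrow for the difference between groups, since the estimated correlation between the list's genes was 0.373. These genes are used by any dividing cell, of tumour or host, so a flat median cannot exclude a smaller share of tumour cells. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty (median 0.128) do not decide, since that reading needs tumour cells with and a host without a Y chromosome, which the labels do not give; Xist was at 265, 123 and 270 CPM in doxycycline replicates 1 to 3 against 108, 122 and 108 untreated. A response to doxycycline, to gavage or to the hairpin remains open, because the groups differ in all of them together, and St18 itself was not lower.

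Of the muscle list 9 of 15 genes, and of the fibroblast list 3 of 16, were higher in the libraries labelled ST18 knockdown. Adjacent skeletal muscle in the specimens stays open: 13 of 15 muscle genes (86.7%) ranked the doxycycline libraries in the order 2, 1, 3, but the order was read from these genes, whose estimated correlation is 0.847, so that a shared response of varying size would give it too. No muscle list gene is in another list, 10 of 15 reached 1 CPM in the untreated libraries, the most abundant were Myh4 (87.0 CPM after doxycycline) and Acta1 (47.7 CPM), and Ttn counts were 11151, 29703 and 4736 in doxycycline replicates 1 to 3 against 590, 2489 and 1009 untreated. Whether 1 admixed tissue brought both groups of genes is open as well, since 4 of 16 fibroblast genes (25%) were highest in replicate 2, but 11 of 16 had an untreated mean above 50% of the doxycycline mean, which would hide a small share. Induction by doxycycline or the hairpin within 4 h cannot be told apart from a difference in dissection, as the summed muscle signal differed 6.25 times between doxycycline libraries and no library had the drug without the hairpin.

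St18 was not lower in the libraries labelled ST18 knockdown. Too few St18 reads to see a fall is argued against for a fall of 1 log2 unit, since the lower bound of the 95% interval was -0.217; it was -0.68, -0.40 and -0.52 without untreated replicates 1, 2 and 3, and -0.57, 0.57 and -0.82 without doxycycline replicates 1, 2 and 3. A library in the wrong group stays open: all 6 libraries correlated better on average with their own group than with the other, by as little as 0.970 against 0.966 for doxycycline replicate 3, and an exchange of the labels of both groups would give the same correlations. St18 reads from host cells, which lack the hairpin, could mask a fall in tumour cells: the rank correlation between St18 and the summed fibroblast list was 0.5 over the 3 doxycycline libraries, too few to decide. A hairpin that had not yet lowered the RNA at 4 h was not tested and stays open.

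The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes higher, 1 split (the real one) reached 421 and the highest other gave 0. For genes lower, 1 split reached 323 and the highest other gave 0. These zeros are edgeR calls, and an unadjusted p under 0.05 was reached by 212 to 1322 genes in the other splits, against 3535 in the real one. Mixed splits place any real group difference within their sides, which by itself lowers the number of calls. For gene lists higher, 4 splits reached the real 3 and the highest other gave 11. For gene lists lower, 2 splits reached the real 9 and the highest other gave 10, so the number of list calls at the preset correlation does not set the real split apart. Which side of a mixed split counts as higher is arbitrary, so its higher and lower list counts can trade places.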

How the results depend on the processing

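St18 was not lower under any alternative. Its log2 fold change ran from 0.58 to 1.45 (adjusted p 0.0386 to 0.639) as each library was left out. The number of genes called depended on the test and on which libraries were included, and the cause was not tested. Against 421 higher and 323 lower genes, DESeq2 gave 887 and 782, limma-voom 1079 and 750, and a threshold of 0.1 gave 894 and 705. Leaving out each library gave 11 to 1244 higher and 12 to 866 lower genes, and 3 to 5 lists higher. The replicate numbers did not pair the libraries (correlations of same-numbered deviations -0.00976, -0.0747 and 0.0155), and a replicate block gave 215 and 179, of which 193 and 159 were shared with the fit without it. Other scalings and filters gave 410 to 535 higher and 277 to 380 lower. Lists called higher numbered 3, against 6 with GC and length offsets (chosen after seeing the data), 0 with an estimated correlation in camera and 1 with fry. Lists called lower numbered 9, against 1 with an estimated correlation and 1 with fry. Removing mitochondrial, ribosomal RNA and haemoglobin genes took out 3 tested genes and moved no count of calls. The listed mitochondrial genes and Rn45s, Rn18s and Rn28s1 were absent from the deposited counts. This alternative could therefore hardly move the counts, and it did not test mitochondrial or ribosomal RNA content. Over 86 named genes and 15 refits, 946 values kept their side of the threshold, 281 lost it and 60 gained it, and none reversed. Over 32 lists 461 kept it, 1 lost it (macrophage markers without doxycycline replicate 3) and 17 gained it. Low counts limit St18 (12 to 61 per library), and the levelling of high counts limits abundant genes.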

Other observations

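The lists in these paragraphs were chosen after seeing the data and are not independent evidence of their direction. Several genes for amino acid handling were lower in the libraries labelled ST18 knockdown. Of 21 aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 10 were lower and none higher (median log2 fold change -0.33), including Wars (-0.61, edgeR adjusted p = 0.00803) and Aars (-0.42, adjusted p = 0.0154). Camera gave an adjusted p of 6.03e-13, and an adjusted p of 0.06 with an estimated correlation. Of 12 amino acid transporter genes, 7 were lower and none higher (median -0.46), including Slc1a4 (-0.96, adjusted p = 0.0075) and Slc1a5 (-0.58, adjusted p = 0.0075). For these camera gave an adjusted p of 1.36e-11, and an adjusted p of 0.00768 with an estimated correlation. That correlation was 0.0146, near the preset 0.01, so the larger adjusted p does not come from the correlation alone. Slc7a5 and Slc7a11 are in both the transporter and the stress response list.

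Of 11 matrix genes of tendon and fascia, 7 were higher and none was lower (median 1.31, camera adjusted p = 4.10e-18, and an adjusted p of 0.00442 with an estimated correlation). Cilp went from 4.96 ± 1.06 to 65.3 ± 12.2 CPM (log2 fold change 3.72, edgeR adjusted p = 8.84e-04), and Fmod rose by 2.97 (adjusted p = 0.00751). In the same libraries 9 of 15 muscle markers (median 3.29) and 3 of 16 fibroblast markers (median 0.60) were higher, and Thbs4, a member of the tendon list, was at 23.1, 58.9 and 9.28 CPM in doxycycline replicates 1, 2 and 3. Of 7 mast cell markers, the protease gene Mcpt4 was higher (3.29) and Kit lower (-0.62), with a camera adjusted p of 0.13. The median of these markers was 2.08, and adjusted over the list alone 5 were higher and 2 lower. Of 10 Schwann cell genes, Scn7a was higher (3.50), with a camera adjusted p of 0.153. None of 4 Y-linked genes passed (median 0.13, camera adjusted p = 0.321).

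Xist was at 265, 123 and 270 CPM in doxycycline replicates 1, 2 and 3, against 108, 122 and 108 in the untreated libraries. Strand use is not given, so how reads shared with its antisense gene were counted is unknown. The summed Y-linked CPM was 592, 646 and 512 after doxycycline and 591, 520 and 484 untreated.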
